A study of Homo sapiens with 6 samples.

How the data were processed

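RNA of 6 samples labelled as SW620 cells, a line derived from a lymph node metastasis of a human colorectal cancer, was measured on 1-colour arrays, 1 array per sample. The labels put 3 samples in a control group and 3 in a group with siRNA against UICLM, a long non-coding RNA. They do not say whether the control cells received a non-targeting siRNA, and they do not say whether replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

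The scanner files hold spot intensity values on a linear scale, deposited as Agilent Feature Extraction version 11.0.1.1 wrote them, per the file headers, with background subtracted and no normalization between arrays. The same program is named in the submitters' processing notes. The authors also deposited a table of the whole series with 17648 probes, all of protein-coding genes. It holds the authors' raw intensities with a floor of 5, their normalized log2 values, an unsigned fold change with its direction, a p-value and an FDR. Per the file headers the arrays were extracted with Feature Extraction. The authors' normalization, test and filter are not given in the sources used here. The FDR column of the deposited table equals a Benjamini-Hochberg adjustment of its p-value column.

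The deposited table was set against the scanner files. Of its 6 columns of single arrays, 4 equalled a scanner array within a relative tolerance of 1e-04, 2 of them under the same replicate number and 2 under another number of the same group. The other 2 columns equalled no scanner array. The table's group values were not the means of its 3 columns per group. Across probes, the deposited log2 difference correlated with the difference of the column means at r = 0.588, and 74.0% of probes had the same sign, where probes are not independent replicates. Which arrays lie behind the deposited statistics therefore stays unknown, and the table was used only as the authors' own comparison and as 1 alternative.

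For the fit, log2 of the processed signal minus each array's 75 percentile over 58945 non-control probes was used. Control and custom spots (2239) were left out, as were 306 probes with an outlier flag on any array. No spot was saturated. Of the 17648 named probes, 170 had such a flag, and probes had to be well above background on at least 3 of 6 arrays. Both steps together left 17397 named probes. Gene names came from the authors' table, brought up to date through the Entrez identifier, of which 17601 (99.7%) matched, so that 1490 symbols were updated. The other 41297 probes of the array had no name in the sources used here. A gene with several probes was represented by its brightest probe, which gave 13446 genes. Among 2781 genes with several tested probes, 1024 (36.8%) had probes with differences of opposite sign. The authors' table lists possible cross-hybridisation for the probes of 2595 genes, among them HSP90AB1, MORF4L2, MOB4 and PTPRO. Coordinates are those of the authors' table on hg19, the build that the headers of the scanner files name for the array design.

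The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes, threshold 0.05), with a second count at a fold of at least 2. Each of 30 gene lists fixed before the data were examined was tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, which tests whether the genes of a list move, on balance, one way. Adjusted p-values of lists are over the 30 lists. The genes named were chosen by a rule fixed before the data were examined. It took the 10 largest rises and falls past the threshold with no overlap between groups, or, where fewer passed, the 10 with the smallest unadjusted p in each direction, given as values; the 2 leading members of each list; and UICLM, ZEB2, CDH1, CDH2, VIM and KRT18. Where no array of a group was well above background, the fold is a bound. It sets the bright group's mean against, per array of the dim group, the higher of the lowest well-measured signal and the dim probe's own.

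The scanner files place the arrays in 3 scan sessions. Session A held 2 control arrays and 1 siRNA array, session B 1 control array and session C 2 siRNA arrays. By their scan times the arrays lay on 4 slides, and no slide held both groups. In session A the siRNA array lay on another slide than the 2 control arrays. Session A was the early scan period, and sessions B and C the late period. The 75 percentile of the signal was 98.2, 130 and 111 for controls 1 to 3 and 503, 117 and 495 for siRNA replicates 1 to 3. The share of probes well above background was 52.7%, 57.9% and 57.9% on the control arrays and 78.6%, 58.3% and 76.9% on the siRNA arrays. The number of arrays limits the precision.

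The fit was tested on simulated data with the real genes' means and 200 changed genes among 13446. With the spread seen within these groups, the share of changed genes called was 0% at log2 changes of 1 and of 2, 18.0% at 3 and 58.0% at 4. With the spread between the 2 arrays of session C, set to the same SD of 0.446 for every gene, it was 20.0% at 1 and 100% at 2. Real genes differ in their spread, so these shares are not those of the real data. A simulated list of 40 genes shifted by 1 on the log2 scale was called, and none of 29 unshifted lists was. The simulated noise was independent between genes and arrays, without the correlation between genes or the scan sessions of the real arrays. It therefore gives no rate of false calls of lists for them.

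Alternatives changed the background correction, the scaling, the filter on dim probes, the treatment of several probes, the variance model, the array weights, the source of the values, the block and the arrays included. The planned normexp correction on mean spot signals was run on the median spot signals, because the scanner files used here hold no mean signal column. A plain t-test as an alternative fit was planned only if the authors' table stated one, and was not run on the scanner values. It was run only on the authors' normalized columns, as a check of their table. The level of UICLM was not analysed here, because no named probe of it was at hand, and CDH1 and CDH2 were not among the named probes.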

Results

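Gene expression in samples labelled as SW620 cells was compared between 3 control samples and 3 samples with siRNA against UICLM, to select mRNAs whose level differs after the knockdown. Values are log2 signals relative to the 75 percentile of each array, and differences are siRNA minus control. The level of UICLM itself was not analysed here, so the knockdown was not checked.

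No gene passed the threshold, and the genes below are given as values with the smallest unadjusted p in each direction. Higher in all 3 siRNA samples than in all 3 control samples was IDH1, the cytosolic isocitrate dehydrogenase (NM_005896, chromosome 2, 209100952 to 209119806), at 2.92 ± 0.07 against −1.06 ± 0.74 (SD, n = 3 per group), a difference of 3.98 ± 0.55 (SE; limma adjusted p = 0.408). The chaperone HSP90AB1 differed by 4.47 ± 0.81 (SE) and was above background on 1 of 3 control arrays. With normexp background correction, whose offset compresses dim signals, its difference was 2.46. The iron exporter SLC40A1 differed by 2.67, the Rab regulator GDI2 by 3.16, MORF4L2 by 2.996 and the splicing factor LUC7L2 by 3.01, with MORF4L2 above background on 2 of 3 control arrays and LUC7L2 on 1. With normexp these differences were 1.33 for MORF4L2 and 1.26 for LUC7L2. No control array was well above background for 4 further genes, so only bounds can be given. They were at least 10.2-fold higher for SLC35F5, 5.44-fold for YIPF3, 5.26-fold for ATP6V0D1, a subunit of the vacuolar proton pump, and 4.08-fold for the deubiquitinase USP25. These bounds hold for the processed signal only, since with normexp the differences were 1.99, 1.15, 1.07 and 1.09 on the log2 scale, which is below them. Within scan session A, which held 1 siRNA array and 2 control arrays, the log2 difference of USP25 was 2.61, against 4.08. These 10 genes had the same adjusted p of 0.408.

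Lower in all 3 siRNA samples were CRAT, carnitine acetyltransferase, with a difference of −4.80 ± 1.09 (SE), ARL6IP4 with −4.01, the receptor kinase ROS1 with −3.76 and the nuclear receptor RORA with −3.52. KRT8, a keratin of simple epithelia, stood at 6.86 ± 0.52 in control and 4.56 ± 0.47 in siRNA samples (SD, n = 3 per group), a difference of −2.30 ± 0.54 (SE). ORAI2, a calcium channel subunit, differed by −2.68, PRSS45P by −2.36 and DPM2 by −2.28. Within scan session A, and so with 1 siRNA array, KRT8 differed by −1.51 and ORAI2 by −1.43. ROS1 and DPM2 were above background on 2 of 3 siRNA arrays and differed by −2.21 and −1.20 with normexp. The brightest probes of MOB4 and the phosphatase PTPRO differed by −3.37 and −2.84, while other probes of these genes reached 2.78 and 2.93. Probes of ARL6IP4 ranged from −4.01 to 0.61 and those of RORA from −3.52 to −0.39. The adjusted p of all 10 was 0.408.

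Over all 13446 genes, limma called 0 at an adjusted p of 0.05, and 0 with a fold of at least 2. At an unadjusted p under 0.05 there were 1501 genes (11.2%), 1195 higher and 306 lower in siRNA samples. This count was 714 without control replicate 1, 2328 without control replicate 2 and 1108 without control replicate 3, and 487, 4833 and 517 without UICLM siRNA replicates 1, 2 and 3. In 2263 genes (16.8%) the groups did not overlap, where chance gives 10% for exchangeable arrays. Of these, 1639 were higher and 624 lower. The filter admits genes well above background in 1 group alone. The share of probes above background was 78.6%, 58.3% and 76.9% on the siRNA arrays, against 52.7% to 57.9% on the control arrays. Whether this adds to the excess of higher genes was not tested. The arrays are not exchangeable, since they part by scan period, and the other 9 splits of them gave 1.67% to 48.7%. The scan session as a block also left 0 genes (1665 at an unadjusted p under 0.05), and the scan period, a block added after the data were seen, left 0 (2370). Without UICLM siRNA replicate 2, the count was 784 genes, 522 higher and 262 lower, and with estimated array weights it was 7728. Leaving out replicate 2 sets 2 siRNA arrays of session C, on 1 slide, against control arrays of other sessions. The weights gave little to the siRNA array scanned early and to the control array scanned late. Neither count can therefore be told apart from a difference between scan sessions.

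**Figure D1:**
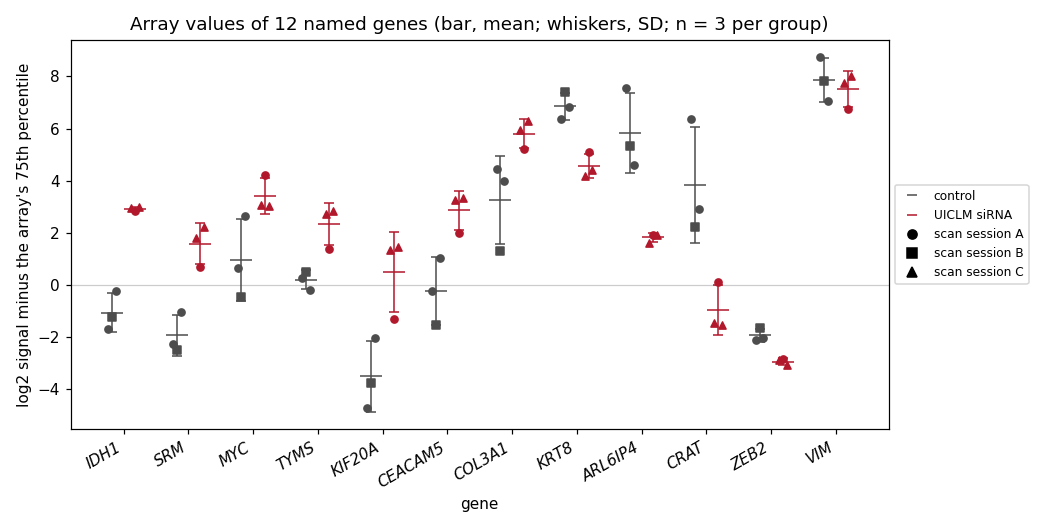
Normalized log2 signal (vertical axis, relative to each array's 75 percentile) of 12 named genes (horizontal axis) on the 3 control arrays (grey) and 3 UICLM siRNA arrays (red). Bars are means, whiskers SD, and marker shapes show the scan session. IDH1 averaged −1.06 in control and 2.92 in siRNA samples, and the VIM values of the groups overlapped.

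The lists of mitosis and of DNA replication genes were higher in siRNA samples. Of 44 measured mitosis genes, 36 had the higher mean in siRNA samples and 8 the lower, with a median difference of 1.52 (camera adjusted p = 7.39e-05). The adjusted p was 0.738 with an estimated correlation and 0.190 with fry. KIF20A, a kinesin of cytokinesis, differed by 3.998 ± 0.96 (SE), or 1.81 with normexp, and PRC1, which bundles the midzone microtubules, by 3.26 ± 0.84. Of 40 DNA replication genes, 31 were higher and 9 lower, with a median of 0.96 (camera adjusted p = 0.00262). The adjusted p was 0.693 with an estimated correlation and 0.118 with fry. RRM1, a subunit of ribonucleotide reductase, differed by 2.84, or 1.31 with normexp, and TYMS, thymidylate synthase, by 2.13. No member of either list passed on its own, also when adjusted over the list alone. The replication call was lost without control replicate 2 (camera adjusted p = 0.0522) and with array weights (0.119). With the scan session as a block the mitosis and replication medians were 0.45 and 0.30, with a camera adjusted p of 0.253 and 0.262, and the differences were 2.07 for KIF20A, 1.73 for PRC1, 1.25 for RRM1 and 1.35 for TYMS. This blocked difference, here and for each list and gene below, rests on session A alone, with 1 siRNA array (replicate 2) against 2 control arrays. It assumes that the lone array varies like the others. That array lay on another slide than the 2 control arrays, so the block does not remove a slide difference.

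The lists of MYC targets and of hypoxia and glycolysis genes were also higher. Of 38 genes of MYC targets and ribosome biogenesis, 28 were higher and 10 lower, with a median of 1.15 (camera adjusted p = 6.49e-04). The adjusted p was 0.722 with an estimated correlation and 0.118 with fry. SRM, spermidine synthase, differed by 3.52 ± 0.65, or 2.27 with normexp, and ODC1, the first enzyme of polyamine synthesis, by 2.71 ± 0.59 (SE). Adjusted over the list alone, 9 members passed, against 0 over all genes. Of 31 hypoxia and glycolysis genes, 24 were higher and 7 lower, with a median of 0.88 (camera adjusted p = 0.00167). The adjusted p was 0.693 with an estimated correlation and 0.0946 with fry. Adjusted over the list alone, 4 of them passed. BNIP3, a mitophagy receptor, differed by 2.54, or 1.14 with normexp, and the pyruvate kinase PKM by 3.04, while its other probe gave 0.09. Array weights ended both calls (camera adjusted p = 0.102 and 0.105), and the authors' normalized columns ended the hypoxia call (0.237). With the scan session as a block, the MYC list had a camera adjusted p of 0.00497 and a median of 0.85, with ODC1 at 1.77, and the hypoxia list 0.0979 and 0.30.

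The lists of p53 targets and of the unfolded protein and ATF4 response passed by a narrower margin. Of 26 p53 targets, 18 were higher and 8 lower (median 0.93, camera adjusted p = 0.0326), and of 39 genes of the unfolded protein and ATF4 response, 26 were higher and 13 lower (median 0.76, camera adjusted p = 0.0348). Both lists had an adjusted p of 0.555 with an estimated correlation, and a fry adjusted p of 0.0147. Among p53 targets CCNG1 differed by 3.04 and TP53I3 by 2.004, or 1.07 with normexp, and 2 members passed when adjusted over the list alone. In the other list the disulfide isomerase PDIA3 differed by 3.13 and DDIT4 by 2.36, or 1.04 with normexp. The p53 call was lost with normexp (median 0.41, camera adjusted p = 0.175) and with probes above background on all 6 arrays (0.28, 0.205). It was lost with the mean over probes (0.80, 0.054), with each probe on its own (0.53, 0.0792) and with the authors' normalized columns (0.60, 0.388). The median was larger with array weights (1.16, 0.244) and without control replicate 2 (1.02, 0.114) or UICLM siRNA replicate 2 (1.14, 0.163), but these calls were lost too. The call of the unfolded protein list was lost with normexp (0.0532), with each probe on its own (0.0792), with array weights (0.154), with the authors' normalized columns (0.244), and without control replicate 2 (0.0522), control replicate 3 (0.0983) or UICLM siRNA replicate 2 (0.141). With the session as a block both had a camera adjusted p of 0.0322, with medians of 0.43 and 0.46, CCNG1 at 1.83 and PDIA3 at 1.88.

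Of 4 lists of markers of other cell types, the fibroblast list passed. Of 13 fibroblast markers, 10 were higher and 3 lower, with a median of 1.02 (camera adjusted p = 0.0473). The adjusted p was 0.738 with an estimated correlation and 0.423 with fry. Within scan session A the median was −0.29, the opposite sign. The call was also lost with quantile normalization (0.0523), median scaling (0.0516), no filter on dim probes (0.108), the mean over probes (0.0671), each probe on its own (0.124), a trended and robust variance (0.0514), array weights (0.244) and the authors' normalized columns (0.577). It was lost without control replicate 2 (0.543), UICLM siRNA replicate 2 (0.0691) or UICLM siRNA replicate 3 (0.0501). The collagen COL3A1 differed by 2.56 ± 0.86 and POSTN by 2.33 ± 0.94 (SE), while within session A these were 0.997 and −0.039. Of 18 leukocyte markers, 4 were higher and 14 lower, with a median of −0.54 that did not pass (camera adjusted p = 0.0578). It passed with quantile normalization (0.0376) and with the scan period as a block (0.0423), and without control replicate 2, control replicate 3, UICLM siRNA replicate 1 or UICLM siRNA replicate 3 (0.0320, 0.0274, 0.0151 and 0.0107). The session block, with its 1 siRNA array, gave 2.13e-04 and a median of −0.90, with CD8A at −0.74. The adjusted p was 0.738 with an estimated correlation. PTPRC, the leukocyte antigen CD45, differed by −1.53 on its brightest probe, while another of its probes gave 0.96, and CD8A by −1.32. Endothelial markers had a median of −0.29 over 10 genes (camera adjusted p = 0.343), with ESAM at 1.32, or 0.19 with normexp, and TIE1 at −1.08. Erythroid and liver markers had a median of −0.67 over 10 genes (0.393), with SERPINA1 at 1.84, or 1.13 with normexp, and ALAS2 at −1.29.

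**Figure D2:**
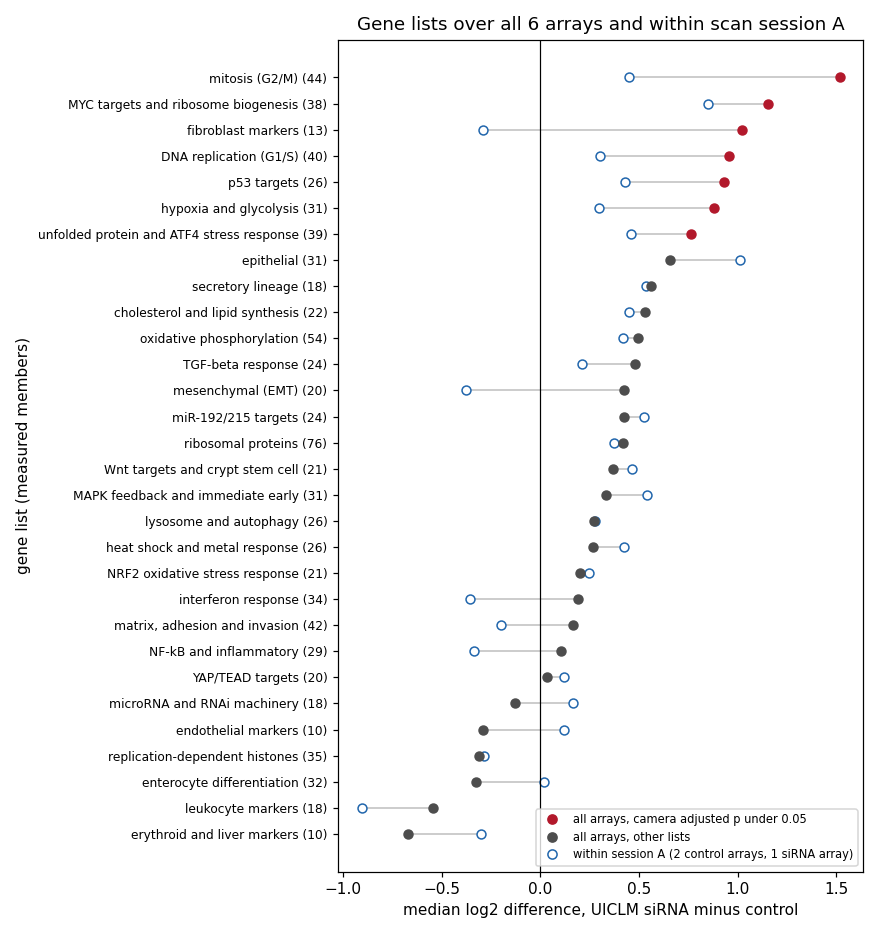
Median log2 difference, UICLM siRNA minus control (horizontal axis), of each of 30 gene lists (vertical axis, measured members in brackets). Filled points are over all 6 arrays, red where camera with a preset correlation passed, and open points are within scan session A, which held 2 control arrays and 1 siRNA array. The mitosis list lay at 1.52 over all arrays and 0.45 within the session, and the fibroblast list at 1.02 and −0.29.

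The lists nearest to the study's question did not pass. ZEB2, a repressor of epithelial genes (NM_014795, chromosome 2, 145141941 to 145277958), stood at −1.94 ± 0.23 in control and −2.94 ± 0.13 in siRNA samples (SD, n = 3 per group). It was lower in 3 of 3 siRNA samples, by −1.001 ± 0.47 (SE; limma adjusted p = 0.453), and was well above background on 2 of 3 siRNA arrays. Within session A it differed by −0.76. VIM differed by −0.36 ± 0.64 and KRT18 by −0.43 ± 0.73 (SE), with adjusted p of 0.763 and 0.752 and overlapping groups, and by −0.029 and −0.13 with normexp. Within session A, which held 1 siRNA array, the KRT18 difference was 1.095 and the VIM difference −1.16, and with the scan period as a block they were −0.068 and −0.54. The mesenchymal list had a median of 0.42 over 20 genes (camera adjusted p = 0.599; TGFB1 at 1.45, or 0.55 with normexp), and −0.37 within session A, with TGFB1 at 0.95. The epithelial list had 20 of 31 members higher and a median of 0.66 (0.197; OCLN at 3.22, or 1.48 with normexp, above background on 1 control array). The camera adjusted p of the epithelial list was 0.0451 with each probe on its own and 0.0464 without control replicate 2. With the session as a block, and so with 1 siRNA array, it was 0.00497, with a median of 1.01 and OCLN at 1.78. With an estimated correlation the adjusted p of the epithelial list was 0.760. Its median was 0.31 with the scan period as a block (camera adjusted p = 0.140). Targets of miR-192 and miR-215 had a median of 0.42 over 24 genes (camera adjusted p = 0.522), with SMARCB1 at 2.86 for its brightest probe, or 1.65 with normexp and 1.42 within session A, and 0.29 for the other.

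Among lists of the bowel epithelium, Wnt targets and crypt stem cell genes had a median of 0.37 over 21 genes (camera adjusted p = 0.393), with MYC at 2.48 and ETS2 at 1.67. With the session as a block, and so with 1 siRNA array, the Wnt list was higher, with a median of 0.47. Without a block, its camera adjusted p was 0.768 with an estimated correlation. Enterocyte genes had a median of −0.32 and a mean of 0.10 over 32 genes (0.915), with CEACAM5 at 3.10 and CEACAM7 at 2.59, or 1.59 and 0.96 within session A. Secretory lineage genes had a median of 0.56 over 18 genes (0.343), with REG4 at 1.81 and TFF3 at 1.98. The TFF3 values of the groups overlapped, and its difference was 0.90 without control replicate 1. Of the signalling lists, MAPK feedback genes had a median of 0.33 over 31 genes (camera adjusted p = 0.343; FOS at 2.78 and SPRY1 at 2.49, or 0.91 with normexp), and 1 passed when adjusted over the list alone. TGF-beta response genes had a median of 0.48 over 24 genes (0.343; TGIF1 at 2.54 and PMEPA1 at 1.86, or 0.44 with normexp), with probes of TGIF1 ranging from −0.33 to 2.76. YAP/TEAD targets had a median of 0.03 over 20 genes (0.781; BIRC5 at 1.97 for its brightest probe and down to 0.35 for others, and ARHGEF17 at least 3.13-fold higher on the processed signal, against a log2 difference of 0.69 with normexp). NF-kB genes had a median of 0.10 over 29 genes (0.781; IER3 at 1.93 and CXCL3 at 1.84). Interferon genes had a median of 0.19 over 34 genes while camera pointed lower (0.944; IFITM3 at 1.67, or 0.29 with normexp). IRF1, not well above background on any control array, turned sign with normexp (−0.20). With the session as a block, and so with 1 siRNA array, the interferon list was lower, with a median of −0.35. Without a block, its camera adjusted p was 0.960 with an estimated correlation. Matrix and adhesion genes had a median of 0.16 over 42 genes (0.538; LAMB1 at 2.57 and ALCAM at 2.21, or 1.24 and 0.40 with normexp). Within session A the difference was 1.30 for LAMB1, 1.64 for TGIF1, 1.51 for ARHGEF17 and 0.78 for IFITM3.

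Of the remaining lists, oxidative phosphorylation had 41 of 54 members higher and a median of 0.49 (camera adjusted p = 0.0794; ATP5F1A at 2.54 and NDUFV1 at 2.05). It passed with normexp (9.85e-04), quantile normalization (0.0189), probes above background on all 6 arrays (0.0338), each probe on its own (0.0451), array weights (0.0175), the authors' normalized columns (0.0398) and without control replicate 2 (5.15e-04), and had 0.00497 with the session as a block. Ribosomal proteins had a median of 0.42 over 76 genes (0.296; RPLP0 at 2.15 and RPL8 at 2.19). Their list passed with normexp (4.89e-04), quantile normalization (0.00509), the authors' normalized columns (7.04e-04) and without control replicate 2 (0.0453), and had 0.0108 with the session as a block. With an estimated correlation the adjusted p was 0.767 for oxidative phosphorylation and 0.832 for ribosomal proteins. With the scan period as a block neither list passed. The medians were then 0.049 for oxidative phosphorylation (camera adjusted p = 0.541) and 0.22 for ribosomal proteins (0.532). Cholesterol synthesis genes had a median of 0.53 over 22 genes (0.343; FDFT1 at 2.85 and HMGCS1 at 1.61, or 0.94 with normexp). Lysosome genes had a median of 0.27 over 26 genes (0.242; PSAP at 2.42, or 1.29 with normexp), and heat shock genes 0.27 over 26 genes (0.312; HSPD1 at 2.66, or 1.66 with normexp). The heat shock list passed with normexp (0.0377) and without control replicate 2 (0.0464), and had an adjusted p of 0.738 with an estimated correlation. Its median was −0.14, the opposite sign, with the scan period as a block (camera adjusted p = 0.644). Adjusted over the list alone, 2 lysosome genes and 1 heat shock gene passed. Genes of the NRF2 response had a median of 0.20 over 21 genes (0.633; NQO1 at 1.70 and GCLM at 1.18). Histone genes had a median of −0.31 over 35 genes (0.343, 0.0434, lower, with the scan period as a block, and 0.767 with an estimated correlation; H1-2 at −1.71 and H2BC4 at −1.58), and microRNA machinery −0.13 over 18 genes (0.915; RAN at 1.57 and AGO2 at 1.36, or 0.73 with normexp). Within session A the difference was 1.26 for FDFT1, 0.96 for HMGCS1, 0.55 for GCLM, 0.82 for RAN and 0.71 for AGO2. Among the list members named, KIF20A, RRM1, BNIP3, SPRY1, PMEPA1, ALCAM and IFITM3 were well above background on 1 of 3 control arrays, and DDIT4, LAMB1, HSPD1 and ESAM on 2. CD8A was well above background on 2 of 3 siRNA arrays.

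The authors' deposited table called far more genes. In the authors' deposited table, 3567 of 17648 probes had an FDR under 0.05, 2586 higher and 981 lower in siRNA samples, and 2224 had an unadjusted p under 0.05 with a fold of at least 2 (1697 higher, 527 lower). Its smallest p-values among higher genes belonged to GRAMD1A (3.09-fold in the authors' deposited table), COPS6 (3.19-fold), XPOT (2.79-fold), a tRNA exporter, and ANAPC11 (2.63-fold), a subunit of the anaphase-promoting complex. FABP6, the ileal bile acid binding protein, was 10.98-fold higher and CD44 3.28-fold higher in that table. Among lower genes in the authors' deposited table were OR10A2 (2.30-fold), BEST4 (5.94-fold), a chloride channel of a subset of colonocytes, VEPH1 (1.98-fold), MRPL52 (2.97-fold) and PRSS45P (4.84-fold). By list, the authors' deposited table had 25 of 44 mitosis genes, 16 of 40 replication genes, 20 of 38 MYC targets and 33 of 76 ribosomal protein genes higher at its FDR and 0 lower. Enterocyte genes had 4 higher and 10 lower of 32, and fibroblast markers 6 higher and 0 lower of 13, in the authors' deposited table. The deposited difference had the same sign as the difference from the scanner files in 77.3% of probes, and in 98.2% of the 3509 tested probes with a deposited FDR under 0.05. Since 4 of the 6 single-array columns equalled scanner arrays, both differences may rest partly on the same arrays. The shared sign is therefore not independent evidence.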

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

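The scan period block, the random session block and the fit to all probes were chosen after seeing the data. The count of 0 genes, and of 0 with a fold of at least 2, held under other background, scaling, filter, probe and variance settings, with the authors' normalized columns and with each block. The exceptions were array weights (7728 genes, 7399 with a fold of at least 2) and leaving out an array, which gave 0 to 784 genes and the same range with a fold of at least 2. The 784 came without UICLM siRNA replicate 2, which sets siRNA arrays of session C against control arrays of other sessions only. The estimated weights were 0.152 for UICLM siRNA replicate 2, 0.234 for control 2 and 6.11 for UICLM siRNA replicate 1, so the fit leaned on few arrays. The 2 arrays of low weight were the siRNA array of the early scan period and the control array of the late period. The weighted contrast therefore largely follows the scan period, and its calls cannot be told apart from a period difference. Gene lists called numbered 7, 2 with array weights, 0 with an estimated correlation, 2 with fry, and 4 to 8 with an array left out (4 without UICLM siRNA replicate 2). With the scan session as a block 9 were called, of which 3 were among the 7, and that contrast rests on 1 siRNA array; with the scan period as a block 9 were called, among them all 7. The ZEB2 level stayed lower in every alternative, at −1.08 to −0.76, and passed with array weights (−0.93, limma adjusted p = 0.0282; other alternatives 0.144 to 0.921); with an array left out it lay at −1.08 to −0.87. The filter for all 6 arrays left it out.

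Of 78 named genes, 73 kept their sign in every alternative, 71 passed with array weights and 36 without UICLM siRNA replicate 2. The last 2 counts come from fits in which group and scan session largely coincide. Differences smaller by over 1.5 times numbered 32 with normexp, 27 with the authors' columns, 26 with the session block, 15 with the random block and at most 7 otherwise. Signs turned for fibroblast markers with the session as a block (median −0.29), IRF1 with normexp (−0.20), MOB4 as the mean of its probes (0.093), POSTN with the session block (−0.039), KRT18 with the session block (1.095) or random block (0.72), and VIM with array weights (0.27). With an array left out, VIM lay at −0.77 to 0.069 and KRT18 at −1.19 to 0.14. The cause was not tested, except that MOB4's probes disagree.

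With the replicate number as a block, 0 genes (727 at an unadjusted p under 0.05), 0 with a fold of at least 2, and 7 lists were called. Deviations of same-numbered samples correlated across genes at −0.30, −0.59 and −0.41. Each of these pairs was scanned in opposite periods, which part the arrays, so this cannot show whether the numbers pair the samples. The weaker signal over background of the control arrays and UICLM siRNA replicate 2 limits dim genes. The UICLM level gave no value, and the plain t-test was not run on the scanner values.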

Other observations

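The tests of exchanged labels, of RNA of other cell types, of tumour and normal bowel tissue, and of other splits for the 2 counts of genes were chosen only after the results were seen. Several abundant transcripts of other cell types gave signals well above background on 6 of 6 arrays, while CD8A and ESAM, of leukocytes and endothelium, did so on 5. COL1A1, the main fibrillar collagen, lay between the percentiles 89.1 and 99.4 of the genes on an array, DCN between 92.9 and 99.1, the haemoglobin chain HBB between 88.6 and 98.3 and CD74, of antigen presentation, between 85.4 and 95.8. LUM ranged from 35.1 to 94.8. Epithelial genes varied, with EPCAM between 92.7 and 95.8 and LGALS4 between 97.6 and 99.8. CEACAM5 lay between 24.2 and 82.8, VIL1 between 29.7 and 64.3 and CDH17 between 20.4 and 64.0. Of the keratins, KRT8 lay between 88.4 and 97.9, KRT18 between 87.8 and 97.9 and KRT20 between 90.1 and 98.8. KRT5, another keratin, lay between 80.8 and 99.7. Probes differ in how well they bind, so these ranks give no relative abundance.

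One technical reading of the bright markers is non-specific signal. The median percentile of 13 fibroblast markers exceeded that of 35 genes restricted to other organs by 17.2 to 53.9 points, at least 20 points on all arrays but 1, which falls short of the bound of 20 points on every array and leaves this open. RNA of other cell types was set to need at least 4 of 8 abundant stromal and blood transcripts in the top 10% on all 6 arrays. Of 7 measured, 1 was in the top 10% on all 6 arrays, so the requirement set for this reading was not met. On at least 5 arrays, 5 of the 7 were in the top 10%. A lower share of such cells would give lower ranks, so the unmet requirement does not exclude RNA of other cell types. A separate hypothesis is that the compared RNA came from tumour and normal bowel tissue, a tissue the labels do not give: of 87 genes listed from background knowledge as differing between colorectal tumour and normal mucosa, 72 had values, and 50 of these passed the FDR of the authors' deposited table, of which 98.0% went the way known of tumour (siRNA) against mucosa (control).

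That table put 22 listed tumour genes higher and 1 lower, and 27 listed mucosa genes lower and 0 higher. Its values were 10.06-fold higher for MMP7, 25.4-fold for KRT23 and 29.2-fold for DPEP1, and 48.7-fold lower for GUCA2B, 45.5-fold for TMIGD1, 28.7-fold for GCG and 41.0-fold for SST, the last 2 being hormones of endocrine cells. Of the listed genes 69.4% passed, against 19.8% of all genes (Fisher's exact test, two-sided, p = 7.11e-20, across genes, which are not independent). Since 29 of the 72 also belong to the 30 lists, whose counts had been seen, the rest were counted alone, and 29 of 30 that passed went that way. In the scanner files the medians were 1.51 for the tumour genes and −0.52 for the mucosa genes, with 24 of 34 higher and 24 of 38 lower, and no gene passed. The table's direction is consistent with tissue RNA (98.0%), but which arrays lie behind it is unknown, and an effect of the siRNA on the same genes was not tested apart from it.

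The arrays grouped by scan period more than by group. Correlations across genes averaged 0.907 within a scan period and 0.761 between periods, 0.841 within a group and 0.805 between groups, and the first principal component (63.4% of the variance) set session A apart. Session A against the others gave 3927 genes. Array brightness alone is argued against, since 41.8% of the 3712 brightest genes were called after quantile normalization, against 29.2% of all genes. So is probe GC content as the whole cause, since 2176 genes stayed called after each array's trend on GC was removed, although the difference correlated with GC at r = −0.46 across genes. In 2 arrays the mean correlation was higher with the other group, which exchanged labels could give; since the scan periods part the arrays the same way, the explanations cannot be told apart.

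The 7 lists higher in siRNA samples were set against the scan session. With the session as a block 3 of the 7 stayed called, and 6 of 7 kept a higher median. With the scan period as a block all 7 stayed called, with medians of 1.14 for mitosis, 0.91 for MYC targets and 1.01 for fibroblast markers, but that block does not part session B, with 1 control array, from session C, with 2 siRNA arrays. The session contrast rests on session A alone, where 1 siRNA array stands against 2 control arrays of another slide. A lost or kept call may therefore come from that array or its slide. The session, the slide and an effect of the siRNA cannot be told apart for these lists. Whether RNA of tumour and normal bowel tissue, the hypothesis raised above, adds to them was not tested.

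The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 genes, also with a fold of at least 2, and the highest other split gave 3927 for both counts. With a real count of 0, counting splits as large decides nothing. The split with 3927 genes parts session A from the other sessions, which points to a structure of the samples that follows the scan. For lists, the real split gave 7 and the highest other 11. At least as many were called in 6 of the 10 splits, the real one included. A count of 7 lists is therefore also reached by splits that do not follow the groups. With the session as a block the gene count was 0.

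Between session A and the others, oxidative phosphorylation genes differed as a list (camera adjusted p = 4.52e-04), with 23 of 54 members lower in session A and 0 higher, but not with an estimated correlation (adjusted p = 0.939). Of 21467 unnamed probes tested between the groups with limma, 0 passed and 1269 had an unadjusted p under 0.05.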
